A study of Homo sapiens with 4 samples.

How the data were processed

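RNA from RD cells, a line established from an embryonal rhabdomyosarcoma, was recovered with biotinylated antisense probes and sequenced. Per the labels, an even and an odd set of probes were directed at exon 2 of ZNF609, and a further set at the bacterial LacZ mRNA as the control. The pull-downs with ZNF609 probes are named for circ-ZNF609, a circular RNA made from that exon. The series holds 4 samples. The sample of total lysate, the input, was not analysed here. Each of the 3 pull-downs was a separate library with its own peak list, so peaks were called per library and not on pooled libraries.

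Per the labels' protocols, RNA was extracted with Qiazol and miRNeasy columns, and libraries were made with the Ovation RNA v2 and Ovation Ultralow v2 kits. Per the submitters' processing notes, bcl2fastq 2.0.2, Trimmomatic, STAR 2.5.2b, bedtools, Picard and SAMtools were used, with the genome build GRCh38. Their roles, order and parameters, and the treatment of duplicate and multiply aligned reads, are not given in the sources used here. The names of the deposited lists name Piranha as the peak caller. Its version, settings and covariates are not given in the sources used here.

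The deposited lists have 8 columns and no header, so the meaning of the columns was read from the values. The signal deposited by the authors is the number of reads in a bin of 170 bases, or the mean over adjacent bins joined into a peak. This reading rests on 100% of peaks having a whole number of reads per peak (tolerance 0.02) and on 100% of peaks lying on a grid of 170 bases. No scaling to library size was seen, and the deposited peaks do not give the total depth of a library. For that reason reads per bin were used to describe and rank peaks within a list. Where reads per bin of several lists are given together they are unscaled, and no difference in recovery is read from them. For peaks outside genes, LacZ peaks were also limited to the unscaled read number of the weakest odd peak. The p-value deposited by the authors was below 0.01 in each peak of the 3 lists, and whether it was corrected for multiple testing is not given in the sources used here. The deposited column 8 is an unnamed score of the bin. It held the same value wherever lists shared an identical peak, and it was a whole multiple of 1/4434 in all peaks (tolerance 0.005 steps) once bins with a fixed value of 0.01 were allowed for. That fixed value equals 44.3 steps and is called the stand-in value here. What the score measures is not given in the sources used here.

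Coordinates are on GRCh38 and count from 1. Each peak was assigned to a gene by the annotated gene spans of RefSeq on GRCh38.p14, with strand ignored, taking the gene with the most overlapping bases then a protein-coding gene and then the shorter gene on ties. The library kits do not keep strand, and the peaks were all listed on the plus strand. Exon, intron and untranslated region positions were not used here, so peaks were placed in genes, or outside annotated genes, and not in parts of genes. Placement by exons had been chosen before the data were examined and was replaced by placement by gene spans. A peak that lies in overlapping genes could not be given to one strand, and 40 even, 44 odd and 62 LacZ peaks lay in more than 1 gene.

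Peaks were counted as shared when they overlapped by at least 1 base. Overlapping peaks of the 3 lists were merged into regions, and each region and each gene was classed by the lists in which it had a peak. The regions and genes found with both ZNF609 probe sets and not with LacZ probes were set beside those found with LacZ probes and 1 ZNF609 probe set, which measure the background in the same way. Shares of peaks are given with exact Clopper-Pearson 95% intervals, which cover counting error alone. There was 1 library per probe set, so no difference has a replicate check and no p-value between probe sets was computed. Peaks and genes are not replicates.

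As a description of chance overlap, the even peaks in genes were placed at random 1000 times within the spans of genes that had a peak in any list. Gene spans include introns, so these placements understate the overlap that random places in spliced RNA would give. For 17 gene lists fixed before the data were examined, the number of members with an even and an odd peak and no LacZ peak was placed among 10000 random draws of as many genes from the 847 genes with a peak in any list. A percentile describes these libraries and is not a test. ZNF609, the target of the probes, was left out of the percentiles of the 2 lists that hold it, a choice made after the data were seen. The list of mitochondrially encoded genes matched 0 annotated symbols, and 5 listed symbols were absent from the gene table used.

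The genes named were chosen by a rule fixed before the data were examined. ZNF609 and CKAP5 were always named. Up to 25 genes were named that had overlapping even and odd peaks and no LacZ peak, in order of the mean of the within-list ranks by p-value. The 5 strongest genes of each of the classes all 3 lists, LacZ alone, even alone and odd alone were named, as were up to 4 members of each gene list. Genes named outside this rule are said to have been chosen after their values were seen. Alternatives tried were a stricter p-value limit, a reciprocal overlap of 50%, a distance of 200 bases, a distance of 1000 bases to LacZ peaks, no subtraction of LacZ peaks, other gene assignments, and lists without chromosome Y, the mitochondrial genome and contigs. Lists trimmed to 502 peaks each, lists without peaks over the stand-in value, LacZ peaks without that value above the read limit, and lists without peaks in more than 1 gene were added after the data were seen.

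Overlaps and percentiles were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9. The overlap step was tested on 1766 simulated peaks in lists of the real sizes and recovered 5 of 5 planted quantities. The percentile step was tested on 800 simulated genes, where 200 random lists had a mean percentile of 50.4 and a planted list had a percentile of 100.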

Results

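RNA captured from RD rhabdomyosarcoma cells with probes against ZNF609 exon 2 was compared with RNA captured with LacZ probes. The LacZ mRNA is bacterial and has no counterpart in human cells, so these probes give the background of the procedure. Of the 4 samples, 3 pull-downs were analysed, with 1 library each, and there was no replicate error for any value. The even list held 502 peaks over 137360 bases, with 482418 reads in peaks. The odd list held 542 peaks over 144500 bases, with 279415 reads in peaks. The LacZ list was the longest, with 722 peaks over 205870 bases and 219401 reads in peaks. The median peak had 293 reads per bin of 170 bases in the even list, 221.5 in the odd list and 115 in the LacZ list, and the weakest peak had 108, 105 and 38.

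The genes that took most reads differed between the lists. ANP32B, which encodes an acidic nuclear phosphoprotein, held 18.3% of the reads in even peaks, with 88380 reads in 6 peaks. PRRC2C followed with 4.16% and the helicase gene DDX27 with 2.17%. In the odd list, the splicing factor gene RBM25 held 2.98%, the cardiac troponin T gene TNNT2 2.34% and OS9 2.10%. In the LacZ list, NACC1 held 4.13%, SGCZ 1.75% and CREBBP 1.45%. PRRC2C, TNNT2 and SGCZ are named here after their values were seen.

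The first comparison asked whether the targeted gene was recovered. ZNF609 had peaks with both ZNF609 probe sets and 0 peaks with LacZ probes. The gene (gene ID 23060) spans chromosome 15, 64459578 to 64686068, on GRCh38. The even probes gave 1 peak at 64499361 to 64500040, 680 bases wide, with 704 reads per bin and a p-value of 3.60e-05, at rank 63 of 502. The odd probes gave a peak at 64499531 to 64500040, 510 bases wide, with 394 reads per bin and a p-value of 1.67e-05, at rank 26 of 542. These peaks shared 510 bases. The odd probes gave 2 further peaks, at 64670381 to 64670550 with 174 reads per bin and at 64673781 to 64674120 with 230 reads per bin. They began 170340 bases downstream of the first odd peak, and the last ended 11948 bases before the end of the gene. Exon positions were not used here, so no peak could be assigned to exon 2. Places 170340 bases apart are too far from each other to lie in 1 exon, so the odd peaks cannot all be from exon 2. Some odd ZNF609 reads thus came from outside the exon of the circular RNA. At the peak shared by even and odd, circular and linear ZNF609 RNA were not separated. The even peak includes a bin with the stand-in value, and ZNF609 had 0 shared regions when peaks over such bins were left out.

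CKAP5, which encodes a microtubule polymerase and is named in the title of the series, was also recovered with both ZNF609 probe sets and had 0 LacZ peaks. The gene (gene ID 9793) spans chromosome 11, 46743048 to 46846280. Each of its 2 peaks was 1 bin wide and occupied the same bin in the even and odd lists. At 46795561 to 46795730 the even peak had 423 reads per bin and a p-value of 7.27e-05, and the odd peak had 269 reads per bin and a p-value of 0.000777. At 46790461 to 46790630 the even peak had 376 reads per bin and a p-value of 9.32e-05, and the odd peak had 197 reads per bin and a p-value of 0.00229. The peaks lay 4930 bases apart. By p-value, the stronger CKAP5 peak was at rank 85 of 502 in the even list and rank 129 of 542 in the odd list.

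**Figure D1:**
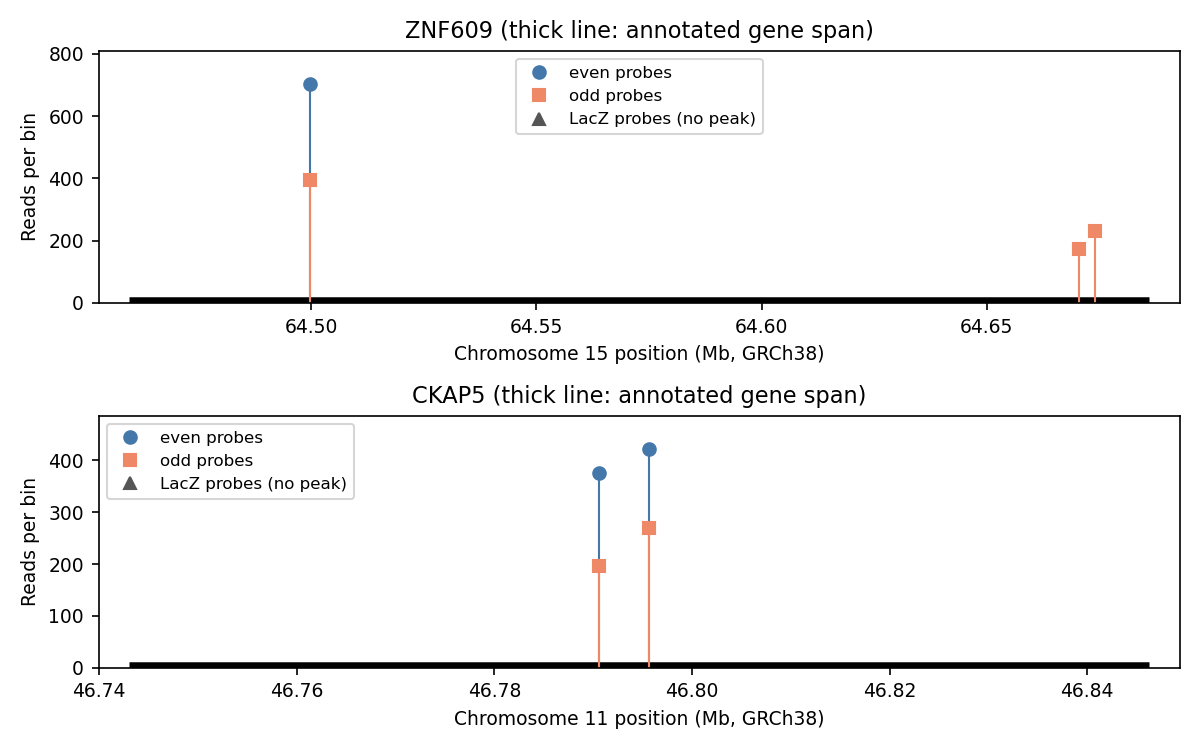
Peaks in ZNF609 and CKAP5, with reads per bin against the position of the middle of each peak in megabases on GRCh38. Circles are even peaks, squares are odd peaks, the thick line is the annotated gene span, and the LacZ list had 0 peaks in both genes. Reads per bin are not scaled to library size.

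The second comparison asked whether the independent ZNF609 probe sets recovered the same regions. Of the 502 even peaks, 93 (18.5%, 95% interval 15.2 to 22.2) overlapped an odd peak, and 74 (14.7%, 11.8 to 18.1) overlapped a LacZ peak. Of the 542 odd peaks, 94 (17.3%, 14.2 to 20.8) overlapped an even peak, and 88 (16.2%, 13.2 to 19.6) overlapped a LacZ peak. In the lists as deposited these intervals overlap for both probe sets. The LacZ list is longer, and in lists trimmed to their 502 strongest peaks, a setting added after the data were seen, the intervals for the even peaks no longer overlapped. There, 18.3% (15.04 to 21.99) of even peaks overlapped an odd peak and 11.6% (8.89 to 14.7) a LacZ peak. For odd peaks in the trimmed lists, 18.5% (15.2 to 22.2) overlapped an even peak and 13.3% (10.5 to 16.6) a LacZ peak, with overlapping intervals. The separation for even peaks was seen in the trimmed lists alone. The intervals overlapped with the stricter p-value limit, without stand-in peaks, with a reciprocal overlap of 50% and with a distance of 200 bases. The LacZ list stayed the longest in those settings, so they do not test the result of the trimmed lists. The 480 even peaks in genes overlapped odd peaks 93 times, against a mean of 1.03 (range 0 to 5) when placed at random in gene spans and 4.95 (range 0 to 12) when placed within their own gene. Their overlap with LacZ peaks was 73, against means of 1.35 and 3.92. The excess over random places was thus seen with the control list as well.

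Merged into regions, 54 were found with both ZNF609 probe sets and not with LacZ probes, and 39 were found with all 3 probe sets. The background pairs gave 35 regions for even and LacZ without odd, and 49 for odd and LacZ without even. Most regions belonged to 1 list, with 374 for even alone, 399 for odd alone and 599 for LacZ alone. Counted by gene, 43 genes had an even and an odd peak and no LacZ peak. The background pairs gave 44 genes for even and LacZ and 56 genes for odd and LacZ. In the lists trimmed to equal length, the order of the gene counts changed, with 49 genes for even and odd, 36 for even and LacZ and 43 for odd and LacZ. The regions there numbered 60, 26 and 35, in the same order as in the deposited lists. With or without a peak in the remaining list, the deposited lists of even and odd shared 87 genes, even and LacZ 88, and odd and LacZ 100. With the stricter p-value limit, which keeps the stronger peaks of each list, the 54 regions became 25 and the 43 genes became 17.

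**Figure D2:**
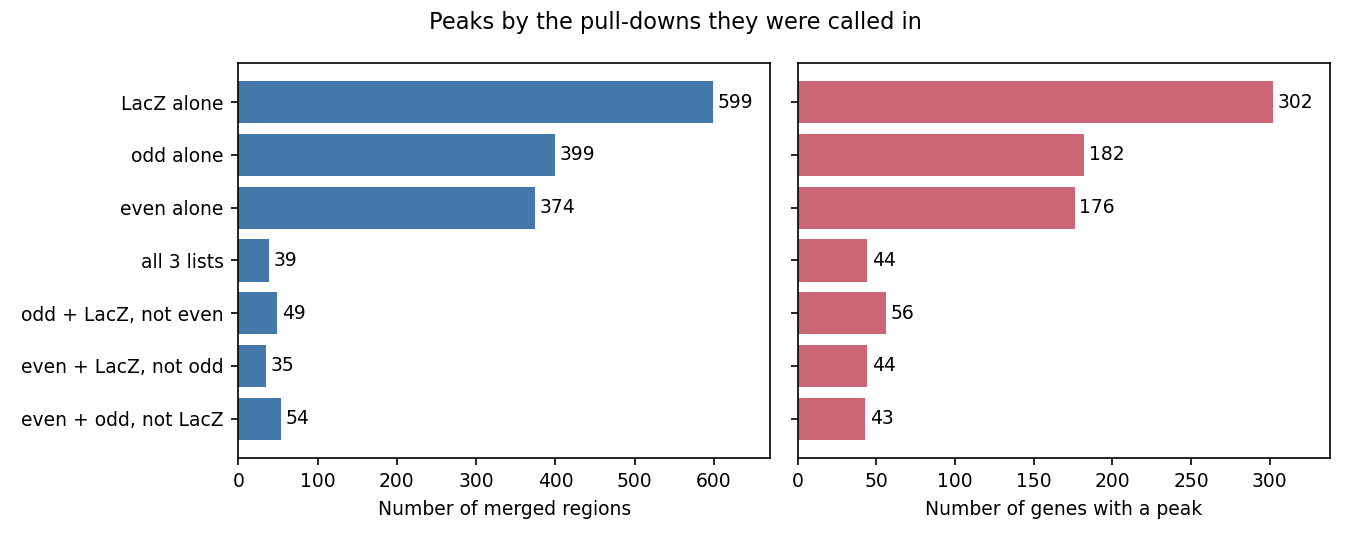
Number of merged regions (left) and genes (right) by the pull-downs in which they had a peak. Regions found with even and odd probes and not LacZ probes numbered 54, against 35 and 49 for the pairs that include LacZ, and the matching gene counts were 43, 44 and 56.

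Among the 54 regions, 30 came from identical peaks in the even and odd lists. Peaks consist of whole bins of 170 bases, and 256 of 502 even and 292 of 542 odd peaks were 1 bin wide. Overlapping 1-bin peaks are identical by construction, so this count does not show agreement to the base. All 54 regions lay in annotated genes. Of these, 41 lay in 30 genes with no LacZ peak, and 13 lay in 12 genes that had a LacZ peak elsewhere. The remaining 13 of the 43 genes had even and odd peaks at different places. After ZNF609, the strongest gene by mean rank was DES, which encodes the muscle intermediate filament protein desmin. Its stronger region, on chromosome 2 at 219418661 to 219419170, had 577.7 reads per bin with even probes and 501 with odd probes. RDX, which encodes the membrane and actin linker radixin, and DDX27, which encodes a helicase of ribosome assembly, followed, each with 2 shared regions. ANP32B also had 2 shared regions, and its even peaks on chromosome 9 at 98015201 to 98015540 and 98012311 to 98012480 ranked 1 and 2 of the even list. The matching ANP32B odd peaks ranked 207 and 231.

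Among the 25 named genes, SRRM1, RAD21, MDN1, PES1 and OS9 also had 2 shared regions and no LacZ peak. SRRM1 encodes a splicing coactivator, RAD21 a cohesin subunit, and MDN1 and PES1 factors of ribosome assembly. The shared regions of RAD21 also lay in LOC112268030 and those of MDN1 in MDN1-AS1, and without strand the genes could not be told apart. In SRRM1 the stronger region, on chromosome 1 at 24671251 to 24671590, ranked 6 in the odd list and 212 in the even list. In RAD21, on chromosome 8 at 116848821 to 116849160, it ranked 46 in the even list and 201 in the odd list. TNNT1, which encodes slow skeletal muscle troponin T, had 1 shared region on chromosome 19 at 55146301 to 55146470, with 345 even and 387 odd reads per bin. UPF2, a factor of nonsense-mediated decay, ranked 17 in the odd list and 301 in the even list, whereas PELP1 ranked 19 in the even list and 321 in the odd list. The other genes named by the rule were HMGN5, KNOP1, NOM1, PLXNA1, TCEAL9, PPIG, HUWE1, HMGB2, MZF1-AS1, GOLIM4 and NAA15. MZF1-AS1 was the 1 long noncoding RNA gene among the 25. With the stricter p-value limit, 11 of the 25 genes still had a shared region, among them ZNF609, CKAP5, DES, RDX, DDX27 and ANP32B, and UPF2, PELP1, OS9 and the genes just listed did not. Annotated pseudogenes carry the names of RDX, ANP32B, SRRM1, RAD21, PES1, KNOP1, TCEAL9, PPIG and HMGB2, so reads of these genes are uncertain where alignment to near-identical copies could divide them.

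Genes recovered with all 3 probe sets were led by LNX2, RBM25, EIF3A, PLEKHA4 and CREBBP. The LNX2 peak occupied the same bases in each list, chromosome 13 at 27583011 to 27583350, with 888.5 reads per bin in even, 248.5 in odd and 633.5 in LacZ. RBM25 held the strongest odd peak, with a p-value of 3.84e-11, and had LacZ peaks at rank 67 and below. CREBBP, which encodes a histone acetyltransferase, had its strongest even and LacZ peaks at the same place, chromosome 16 at 3849311 to 3849650. The strongest genes of the LacZ list alone were NACC1, NELFA, XAB2, CHLSN and CCDC50. The NACC1 peak at chromosome 19, 13138111 to 13138620, had 2203 reads per bin. The even list alone was led by RPTOR, UPF3B, EPHA7, ZFP91 and DHX38, and the odd list alone by ITSN1, HMGN1P38, HMGN1, PRRC2A and UBA2. HMGN1P38 is a pseudogene of HMGN1, and reads of the pair may not be separable.

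The third comparison asked in which kinds of gene the peaks lay. Peaks in protein-coding genes made up 94.4% (95% interval 92.0 to 96.3) of even peaks, 97.4% (95.7 to 98.6) of odd peaks and 84.6% (81.8 to 87.2) of LacZ peaks. Peaks in long noncoding RNA genes made up 1.2%, 0.923% and 3.74%. Strand was ignored and ties went to protein-coding genes, so the 40 even, 44 odd and 62 LacZ peaks in more than 1 gene may hide such RNAs. The intervals do not cover that. Peaks outside annotated genes made up 4.38% (2.77 to 6.56) of even, 1.11% (0.407 to 2.39) of odd and 10.9% (8.76 to 13.4) of LacZ peaks, so the LacZ share in the deposited lists lay above both ZNF609 shares beyond counting error. The LacZ list had 6 peaks on chromosome Y or contigs, against 0 in the even and odd lists. The share outside genes was not recomputed without them. Without peaks over bins with the stand-in value, the shares outside genes were 0.674% (0.139 to 1.96), 0.577% (0.119 to 1.68) and 4.52% (2.95 to 6.60). When the LacZ peaks without that value were also limited to those with at least the 105 reads per bin of the weakest odd peak, 4 of 232 (1.72%, 0.472 to 4.36) lay outside genes, and the difference from the ZNF609 lists was no longer detectable. That setting was added after the data were seen. The mitochondrial genome held 0 peaks in the 3 lists.

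Gene lists fixed before the data were examined were then counted. Of 82 annotated microtubule and spindle genes, 22 had a peak, with 9 in the even, 10 in the odd and 14 in the LacZ list. CKAP5 and the dynein intermediate chain gene DYNC1I2 were the 2 with even and odd peaks and no LacZ peak, against 1.1 in random draws (percentile 80.1). MAP1B and DCTN1 also had regions shared by even and odd and absent from LacZ, and each had 1 LacZ peak elsewhere in the gene. The other microtubule genes with LacZ peaks included MAP1A with 4 and INCENP with 6 LacZ peaks, named after their values were seen. Of 35 genes in the actin cytoskeleton list, which also holds genes of other cytoskeletal proteins, 15 had a peak. These were 10 in the even, 11 in the odd and 8 in the LacZ list. AHNAK, CALD1 and MYH10 had even and odd peaks and no LacZ peak, against 0.756 in draws (percentile 98.0). In each of these 3 genes the even and odd peaks lay at different places. A further 4 members of the actin cytoskeleton list had peaks in all 3 pull-downs, a class for which no percentile was computed. Of these, MYO10 and PLEC had regions shared by even and odd and absent from LacZ. Of 46 myogenic and muscle genes, 9 had a peak, with 5 in the even, 5 in the odd and 4 in the LacZ list. DES and TNNT1 had even and odd peaks and no LacZ peak (percentile 96.0). With 17 lists counted, percentiles of this size can arise in some list by chance.

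The chromatin and transcription list had peaks in 25 of 53 members, with 14 in even, 14 in odd and 12 in LacZ. Without ZNF609, which the probes target by design, 2 members without a LacZ peak were recovered with both ZNF609 probe sets (percentile 77.1). These were CHD4 and HUWE1, of which HUWE1 encodes a ubiquitin ligase. RNA binding and splicing genes had peaks in 17 of 56, with SRRM1 and SRSF11 in the shared class (percentile 87.0). Translation factors had EIF4G1 (percentile 84.9) and cell cycle genes RAD21 (percentile 82.1) in that class. In CHD4, SRSF11 and EIF4G1 the even and odd peaks lay at different places, so no region was shared. Of 597 annotated ZNF genes, 8 had a peak, and apart from the targeted ZNF609 there were 0 in that class (percentile 35.4). The extracellular matrix and adhesion genes had 9 members in the LacZ list, 5 in the even and 3 in the odd list. Those lists held 446, 307 and 325 genes in all. In the shared class these genes had 0 members (percentile 27.9). Heat shock (percentile 40.8) and glycolysis genes (percentile 42.9) also had 0 members there. Of 86 ribosomal protein genes RPL7 alone had a peak, in the LacZ list (percentile 47.5), and of 90 histone genes H1-1 had a LacZ and H1-3 an odd peak (percentile 45.1). The lists of structural noncoding RNAs, long noncoding RNAs, and immune and blood markers had 0 members with a peak. Peaks went to the gene with the most overlapping bases and then to a protein-coding gene. Short RNAs that lie inside other genes could be missed in this way, so these counts do not show that they were not captured.

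**Figure D3:**
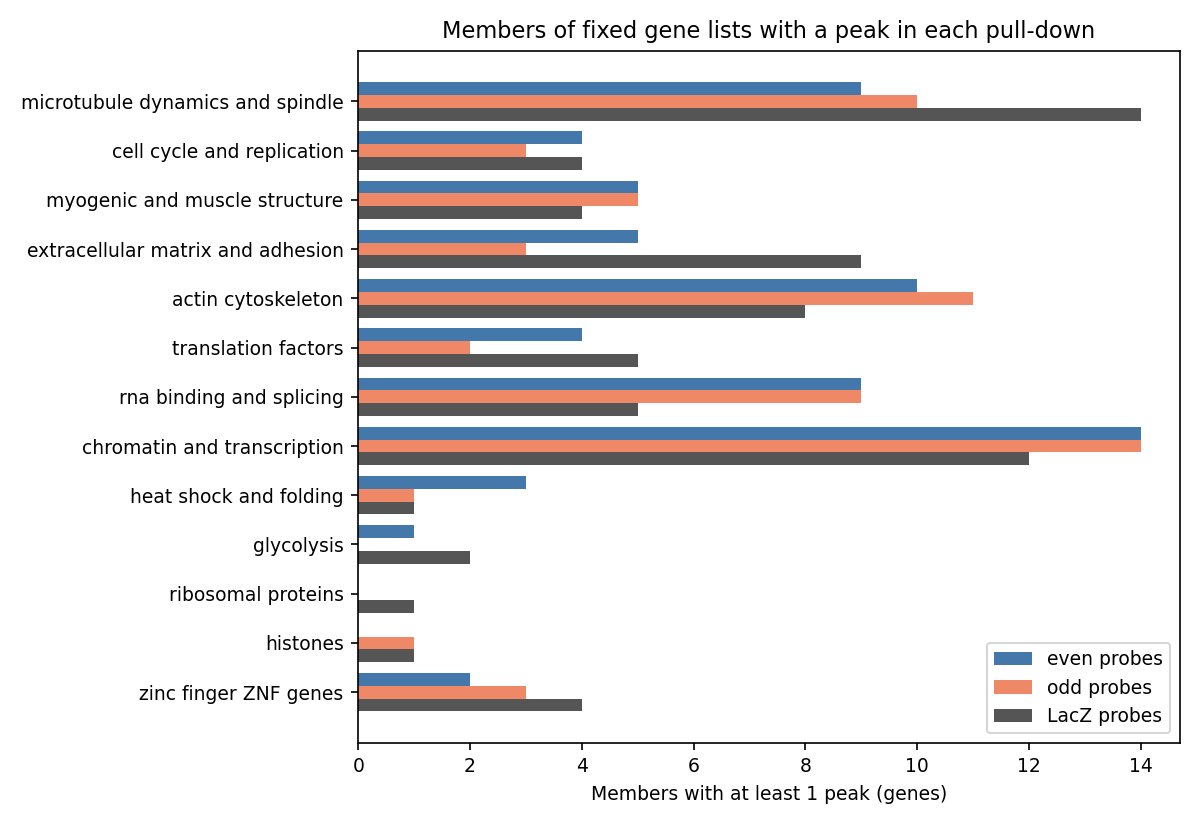
Number of members of each fixed gene list with at least 1 peak in the even, odd and LacZ lists. Lists with no member with a peak are left out, and the microtubule list had 9 even, 10 odd and 14 LacZ members.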

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

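The test of the stand-in value was chosen after the values were seen. Column 8 was the measure of no comparison in the report, though gene classes are compared by it under the other observations. It held a fixed value of 0.01 in bins under 57 even peaks (11.4%, 95% interval 8.71 to 14.5), 22 odd peaks (4.06%, 2.56 to 6.08) and 169 LacZ peaks (23.4%, 20.4 to 26.7). Among these was the even peak of ZNF609.

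Single-bin peaks over the stand-in value began at higher read numbers than those in bins with a low score. The lowest had 336 reads in the even, 300 in the odd and 107 in the LacZ list, against 108, 105 and 38 for peaks in bins at 1 step of the score. In bins at 40 to 49 steps, near the size of the stand-in, the lowest were 314, 276 and 101. The smallest of the 3 ratios between stand-in and 1-step bins was 2.82. These values are consistent with the stand-in having entered the peak caller as a high covariate, so that bins with no counted value may have needed more reads than bins with a low one. The even ZNF609 peak spans 4 bins, of which 1 held the stand-in value. No biological explanation was tested.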

How the results depend on the processing

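The trimmed lists, the lists without the stand-in value, the read limit on LacZ peaks and the lists without peaks in more than 1 gene were added after the data were seen. Over 14 alternative settings, 197 values stayed close to the reported value and 38 moved. Close means inside the 95% interval for a share of peaks, within 1.5 times for a count or a mean of placements, and an equal count for the regions of a named gene. The stricter p-value limit, which leaves about 50% of each list, lowered the regions shared by even and odd without LacZ to 25, by even and LacZ to 20, and by odd and LacZ to 16. The matching genes fell to 17 (14 of the 43 kept), 24 (17 kept) and 27 (21 kept), and the share of odd peaks overlapping LacZ was 11.1%. These falls follow in part from fewer peaks. Without subtraction of LacZ peaks, 93 regions were shared by even and odd. In lists trimmed to 502 peaks, 11.6% (8.89 to 14.7) of even peaks overlapped LacZ and 18.3% (15.04 to 21.99) overlapped odd, so these intervals separated. They overlapped in the deposited lists, with the stricter limit, without stand-in peaks, with a reciprocal overlap of 50% and within 200 bases, and for odd peaks in each of these settings. Outside the trimmed lists the LacZ list stayed the longest. The compared shares are of the same peaks, so neither separation nor overlap of the intervals is a test. Without stand-in peaks, 0.674% of even and 4.52% of LacZ peaks lay outside genes, and 1.72% of LacZ peaks with the read limit as well. Random placement within the same gene gave 4.95 overlaps. Of the 25 named genes, 11 kept a shared region with the stricter limit, 21 with a reciprocal overlap of 50% (not HMGN5, KNOP1, TCEAL9 and PPIG) and 24 without stand-in peaks (not ZNF609). CKAP5 kept its 2 regions in each of these settings. A same-strand rule moved nothing, since the peaks were all listed on the plus strand. Leaving out chromosome Y, the mitochondrial genome and contigs also moved nothing, since the even and odd lists had 0 peaks there and the LacZ list 6. The unmoved values of these settings are counted among the 197, though they had little or no room to move. Exon overlaps only, the region holding most bases of a peak, and placement within exons were not run, because exon positions were not used here. Depth beyond the reads in peaks is unknown, so a gene without a LacZ peak is not shown to lack LacZ signal. No paired analysis was possible because each probe set had 1 library.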

Other observations

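Families chosen after the values were seen showed further recovered RNAs. Of 4 annotated ANP32 genes, ANP32A, ANP32B and ANP32E had even peaks, ANP32A and ANP32B had odd peaks, and 0 had LacZ peaks. Of 9 HMG box and HMGN genes, HMGB2 and HMGN5 had even peaks, HMGB2, HMGN1 and HMGN5 had odd peaks, and 0 had LacZ peaks. Of the UPF genes of nonsense-mediated decay, UPF2 had peaks with both ZNF609 probe sets, UPF3B had even peaks alone, and 0 had LacZ peaks. The DEAD and DEAH box helicases had 7 even, 2 odd and 4 LacZ members of 62, and DDX27 was shared by even and odd without LacZ. Of 112 ribosome assembly genes, 16 had even, 14 odd and 14 LacZ peaks, and 5 (DDX27, MDN1, NOM1, PELP1 and PES1) had even and odd peaks without LacZ. That list was written after these genes had been seen, so its count is no evidence of enrichment. The other families counted had LacZ peaks as well, with 2 even, 2 odd and 1 LacZ member for troponin T, the same numbers for GPATCH genes, 5, 4 and 4 for nonmuscle and unconventional myosins, and 2, 4 and 2 for dynein and dynactin genes.

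Some muscle RNA was recovered with all probe sets. TNNT2 had 5 even, 8 odd and 5 LacZ peaks, and 5 of its peaks were identical in the 3 lists. Of 19 peaks identical in the 3 lists, in 12 genes, CHAF1A and CREBBP each held 2 and RBM25 held 2. These genes were chosen after their values were seen, apart from RBM25 and CREBBP.

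The test of the genes shared by even and LacZ alone, and the placement of genes without a step value, were chosen after the values were seen. In the deposited lists, even shared about as many genes with LacZ (88) as with odd (87), and capture of more abundant RNAs with any probe set stays open as an explanation, if column 8 follows RNA abundance, which the lists do not state. Genes in all 3 lists had 2.18 times the median steps per bin of genes in 1 list (95% bootstrap interval 1.23 to 3.36), and genes of even and LacZ without odd 1.4 times (0.906 to 1.96), but 121 of the 660 genes in 1 list had stand-in peaks alone and were left out. With those genes at 0 the ratios were 3.28 (1.92 to 5.12) and 2.1 (1.32 to 2.93), and with them at the size of the stand-in they were 1.49 (0.846 to 2.30) and 0.977 (0.643 to 1.41), so the outcome depends on what the stand-in means. The longer LacZ list also stays open, since after trimming the 49 even and odd genes were 1.36 times the 36 even and LacZ genes, between the bounds set before. The 43 genes of even and odd without LacZ had a median of 14 steps per bin (quartiles 7.83 to 23.5). The medians were 14.25 for odd and LacZ without even, 10.5 for even and LacZ without odd and 7.5 for genes in 1 list. Column 8 thus did not set the even and odd class apart from the background pairs, and RNA abundance stays open for that class as well. RNAs bound to circ-ZNF609 stay open as a biological explanation of the even and odd class, though circular and linear ZNF609 RNA were not separated. Sequence identity to the probes, base pairing and base composition were not analysed here.

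The larger share of LacZ peaks outside annotated genes was weighed against the stand-in value and against low read numbers, and the tests of the stand-in value and of read numbers without it were chosen after the share was seen. Without stand-in peaks, which were 54 of the 79 LacZ peaks outside genes, the LacZ share was 4.52% (2.95 to 6.60) against an even share of 0.674% (0.139 to 1.96), which argues against the stand-in as the whole cause. Among LacZ peaks with at least the 105 reads per bin of the weakest odd peak, 58 of 401 (14.5%, 11.2 to 18.3) lay outside genes, but this limit kept each of the 169 stand-in peaks and raised their share from 23.4% to 42.1%, so it decides nothing. With that limit and without stand-in peaks, 4 of 232 LacZ peaks (1.72%, 0.472 to 4.36) lay outside genes, within the interval of the even share, so low read numbers may account for the excess apart from stand-in peaks. Reads are not scaled between libraries, the interval is wide, and no biological explanation was tested.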
